A study of Vitis vinifera with 165 samples.

How the data were processed

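Berries of Pinot noir, a red wine grape (Vitis vinifera), were collected near Modesto, California, from vines of clone FPS 23 on Freedom rootstock, in the seasons 2012, 2013 and 2014. Per the labels, clusters were removed after fruit set to take off 50% or 75% of the crop. Each sample was a pool of 60 berries from 6 clusters, drawn from blocks of 8 vines in 9 vineyard rows, with 3 rows per treatment. The berries were ground in liquid nitrogen and the seeds were taken out, which left the pericarp, the skin and flesh. Libraries were made per the labels with the non-directional TruSeq protocol from 2.5 micrograms of total RNA, so reads from a gene and from an overlapping antisense gene were not told apart. The labels also describe an unthinned control, which was not analysed here. Sugar content in g per 100 ml and the day relative to veraison, the onset of ripening and colour change, were taken from the labels of each sample.

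The authors deposited gene expression as RPKM, reads per kilobase of gene model scaled to the mapped reads of the library, in a table of 29971 gene models and 165 libraries. The submitters' processing notes name TopHat2 2.0.6 and Cufflinks 2.0.2, without saying what each step did. The genome build and the settings were not given in the sources used here. RPKM values carry no read counts, and gene lengths were not used here, so the depth of each library is unknown and no counting error was computed. Total RPKM per library lay between 876732 and 1405120 with a median of 981285, and 14835 to 17668 gene models reached an RPKM of 1. Of 5842 gene models with a median RPKM above 20, 96 were listed at 0 in at least 1 library. Whether such a 0 is a failed estimate or low expression at some stage or season was not checked. It is therefore given below only as listed at 0. Reads shared between near-identical gene copies could be divided between them in these values, and single gene models of such families are uncertain.

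Samples were grouped by season, thinning and time point, which gave 55 groups of 3 libraries. No pair of libraries held identical values, and the highest correlation between libraries of different groups was 0.994. Replicates of a group correlated with a median Pearson r of 0.987 across genes (range 0.915 to 0.992). The labels do not say which row or block a replicate number stands for, so p-values measure the spread between these pooled samples only. Thinning was compared on the 26 days sampled in both treatments (7 in 2012, 9 in 2013 and 10 in 2014). The last point of 2012 fell on day 42 at 50% and on day 34 at 75% thinning, and day 38 of 2014 was sampled at 75% only, and neither entered a comparison.

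RPKM values were tested as log2(RPKM + 1), so a fold change is on that scale and understates the change of low gene models. The 20460 gene models with an RPKM of at least 1 in at least 3 libraries were tested. limma 3.58.1 in R 4.3.3 fitted 1 mean for each of the 55 groups, with an intensity trend, 110 residual degrees of freedom and 3.24 prior degrees of freedom. All adjusted p-values of gene models are from limma with Benjamini-Hochberg adjustment over the gene models tested. Where counts below an unadjusted p of 0.05 are given, a share of 0.05 of the 20460 gene models is expected there without any difference. Thinning contrasts were called at an adjusted p of 0.05. Ripening and season contrasts were called at the same adjusted p and an absolute log2 change of at least 1. Thinning was averaged over the matched days of a season and over the seasons with equal weight, and also within 3 phases, before veraison, veraison to day 14, and day 21 to harvest. Ripening was day 21 minus day -14, or minus day -18 in 2012. Differences of the thinning effect between phases, and between 2 days of 2012, were added after the data were examined.

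A ripening score was computed for each library as the mean log2 value of the 100 gene models that rose most minus that of the 100 that fell most in both other seasons, so that no gene model was chosen on the season scored. Sugar content and score were compared between thinning levels by two-sided permutation tests with 100000 resamples of the thinning labels within each day, whose smallest p is 1e-05. Tests of sugar and score by phase and between phases were chosen after the results were seen. Tests of sugar and score by phase, and of the differences between seasons or phases, were adjusted over 12 tests each. Those by phase included all matched days. They also included veraison to day 14 without day 14 of 2014, and without replicate 2 of 75% thinning on day 0 of 2012. Tests adjusted together thus share samples. Overlaps of called gene models were tested by Fisher's exact test, two-sided, adjusted over 28 tests. Expected numbers were taken over all gene models tested. They were not matched for expression level or spread, on which both kinds of call can depend.

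Apart from the additions named above and below, the choices of groups, tests, thresholds and most alternatives were made before the data were examined. The alternatives were a pseudocount of 0.1, no filter on low values, quantile normalization, replicate number within season as a block, leaving out each replicate number in turn, sugar content as a covariate, plot means (log2 values averaged over days for each season, thinning level and replicate number) and, for the score, 30 gene models per direction. Alternatives added later left out single days, single libraries or gene models. The rule for naming gene models was to take those with the largest rise and fall among the called ones, for thinning only those with the same sign in all 3 seasons. It asked for informative names, but the files pair the gene model IDs with no names and 0 of the IDs matched the reference table, so at most 2 IDs per direction were named in a comparison. None were named for single seasons and days, for the 2 earlier phases or for thinning by ripening, and for the seasons those named are a selection from the gene models that the rule allowed. For the same reason the 24 lists of gene families fixed before the data were examined, among them markers of seed tissue, could not be matched and were not tested.

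Thinning over the seasons, in 2012, from veraison to day 14 and on day 21 of 2013, ripening, 2014 against 2013, thinning by ripening and thinning by season were checked on simulated data. The other contrasts use the same model and were not simulated. The simulated data kept the measured group means and spread of the 20460 gene models, with the contrast tested set to 0 and 200 gene models changed. Normal noise was drawn independently for each gene model and library, without deviating libraries and without dependence between gene models or days. The calls among unchanged gene models below therefore do not measure how many false calls the real data give. For thinning over the seasons, 49.3% of changes of 0.1 log2, 85.1% of changes of 0.2 and 97.0% of changes of 0.4 were called, with 13 calls among unchanged gene models. For a single day (day 21 of 2013), 43.3% of changes of 0.5 log2, 79.1% of changes of 1 and 97.0% of changes of 2 were called, with 9 calls among unchanged gene models. For ripening, all changes of 1.5 and 3 log2 were called. Permutation tests and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R read the files with the data.table package, version 1.17.8.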

Results

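Expression in the pericarp of Pinot noir berries was followed through ripening in 3 seasons on vines with 50% or 75% of the clusters removed. The 165 libraries formed 55 groups of 3, from day -28 to day 42 around veraison in 2012, from day -14 to day 37 in 2013 and from day -14 to day 49 in 2014. The question set by the design was how the strength of cluster thinning affects berry ripening. The depth of the libraries is unknown, since the files give RPKM only. The first principal component of all libraries held 57.9% of the variance, and the next components held 11.6% and 6.4%.

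Sugar rose from 0.57 ± 0.01 g per 100 ml (SD, n = 3) on day -28 of 2012 to 20.6 ± 0.1 on day 21 at 50% thinning. Berries at 75% thinning held more sugar over the matched days of 2012, by 0.71 g per 100 ml (12.0 against 11.3, 21 samples each, permutation test, p = 0.00329). In 2013 the difference was 0.52 g per 100 ml (16.4 against 15.9, 27 samples each, permutation test, p = 0.0498), and in 2014 it was 0.21 (15.2 against 15.0, 30 samples each, permutation test, p = 0.485). No difference between seasons passed its own test (permutation test, lowest adjusted p = 0.307). In tests by phase, chosen after the results were seen, 75% berries had 1.16 g per 100 ml more sugar from veraison to day 14 (13.9 against 12.7, 24 samples each, higher on 7 of 8 days, permutation test, adjusted p = 0.0003). Before veraison the difference was -0.19 (adjusted p = 0.229) and from day 21 to harvest 0.52 (adjusted p = 0.111) in the same permutation test. The difference from veraison to day 14 exceeded that before veraison by 1.35 g per 100 ml (permutation test, p = 1e-05, the smallest the resamples can give, adjusted p = 0.00012). The 2013 difference missed the threshold without replicate 1, 2 or 3 (p of 0.051, 0.221 and 0.0818), and the 2012 difference without replicate 2 (0.56, p = 0.0855), all by permutation test. The 2014 difference was -0.15 without replicate 2. These permutation tests, and those of the score below, treat samples of different days as independent, although each treatment had 3 rows. Paired by replicate number, the sugar difference had an exact sign-flip p of 0.25 in 2012, 0.25 in 2013 and 0.75 in 2014. The smallest p that 3 pairs allow in the sign-flip test is 0.25.

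The ripening score, built from gene models chosen in the other seasons, rose from -5.58 ± 0.06 (SD, n = 3) on day -28 to 6.79 ± 0.10 on day 21 of 2012 at 50% thinning. Over a whole season the score at 75% minus that at 50% thinning was 0.00 in 2012, -0.11 in 2013 and 0.10 in 2014 (permutation tests, p of 0.98, 0.48 and 0.487). That of 2012 took either sign under the alternatives, from -0.11 to 0.15. The difference from veraison to day 14 exceeded that before veraison by 0.80 log2 units (permutation test, adjusted p = 0.0262). Neither phase passed alone, with 0.33 from veraison to day 14 and -0.48 before veraison (permutation test, adjusted p = 0.0769 each). The positive difference was 0.15 (p = 0.408) without day 14 of 2014, and 0.38 (adjusted p = 0.0456) without replicate 2 of 75% thinning on day 0 of 2012, in the same permutation test. The tests adjusted together include this phase with and without these samples, which can lower that adjusted p.

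**Figure D1:**
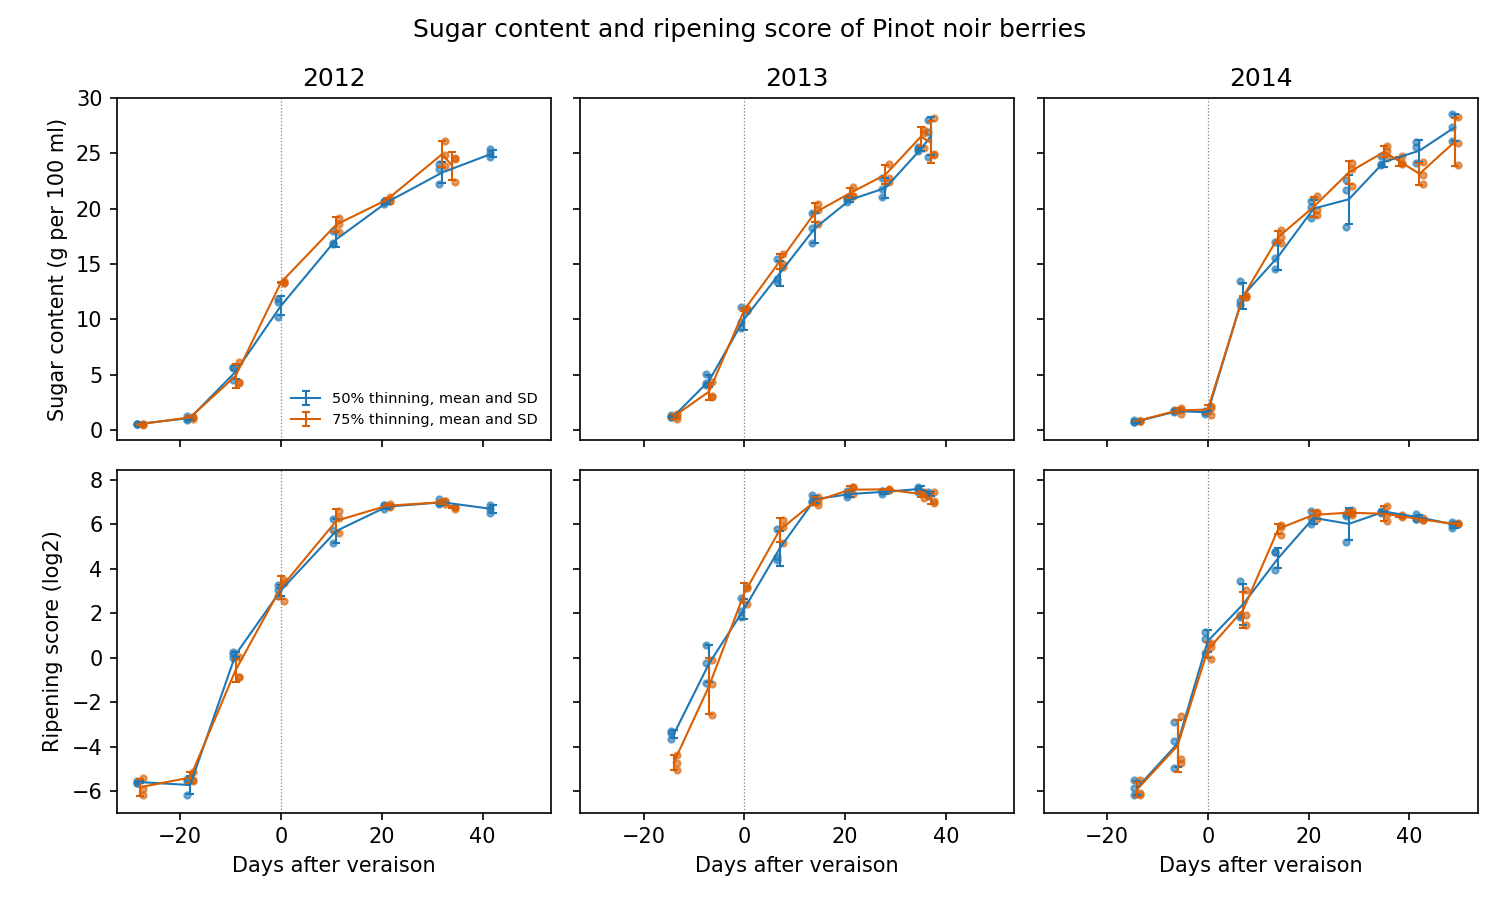
Sugar content in g per 100 ml (upper panels) and ripening score in log2 units (lower panels) against days after veraison in 3 seasons at 50% (blue) and 75% (orange) thinning; points are samples, shifted sideways by treatment, and lines join group means with their SD (n = 3). Sugar stayed between 1.4 and 2.15 on day 0 of 2014, while the score of the same samples lay between -0.04 and 1.18.

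Ripening changed the expression of 6124 of 20460 gene models between the green stage and day 21, of which 1567 rose and 4557 fell. The same direction was called in each of the 3 seasons for 1065 risers and 3320 fallers. VIT_11s0016g04920 rose from 13.8 RPKM (listed at 0 in 1 of 18 libraries, up to 75.0) to 13100 ± 1549 RPKM (SD, n = 18), a log2 change of 10.90 ± 0.28 (SE, limma, adjusted p = 1.03e-66). VIT_02s0025g04300 rose from 8.77 ± 9.13 to 11154 ± 2352 RPKM (SD, n = 18), by 10.72 ± 0.26 (SE). VIT_06s0004g04640 fell from 1791 ± 413 to 3.63 ± 2.41 RPKM, and VIT_02s0154g00320 fell from 966 ± 782 to 1.19 ± 0.69 RPKM (SD, n = 18 each), with log2 changes of -8.72 ± 0.22 and -8.50 ± 0.15 (SE). On day 0 of 2012 VIT_11s0016g04920 already stood at 6773 ± 88 RPKM at 50% thinning, against 1284 ± 768 in 2013 and 2397 ± 539 in 2014 (SD, n = 3 each).

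The median log2 change of all gene models in ripening was -0.30. After quantile normalization it was 0.06 and the calls were 2596 higher and 2960 lower, so the excess of fallers is relative to the authors' scaling. The named gene models kept their calls under all 8 alternatives.

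Between severe and moderate thinning 594 gene models were called over the matched days of the 3 seasons, 141 higher and 453 lower at 75% thinning. Of 100 splits that moved single libraries within days, the real one included, 3 gave as many calls. Of 100 that moved all libraries of a replicate number within a season together, 16 did, so chance was not excluded at that level. The differences were small, with a median absolute log2 difference of 0.14 among the called gene models and 0.66 at most. VIT_01s0011g02710 was lower by -0.62 ± 0.10 log2 (SE, limma, adjusted p = 3.23e-05), with differences of -0.63, -0.74 and -0.48 in 2012, 2013 and 2014, and lay lower on 23 of 26 days. On day 21 it stood at 6.50 ± 2.61 RPKM at 75% against 16.8 ± 7.5 at 50% thinning in 2012, 10.5 ± 5.2 against 37.0 ± 9.9 in 2013 and 3.17 ± 0.83 against 8.48 ± 0.67 in 2014 (SD, n = 3 each). VIT_08s0040g00920 was also lower (-0.66 ± 0.16 SE, limma, adjusted p = 0.00776), while VIT_18s0001g11520 (0.44 ± 0.11 SE, limma, adjusted p = 0.0151) and VIT_08s0040g00490 (0.40 ± 0.09 SE, limma, adjusted p = 0.00367) were higher. Among the 453 lower gene models, 172 also fell in ripening where 101 were expected, and 95 rose where 34.7 were expected. These overlaps had adjusted p of 5.15e-14 and 3.23e-19 by Fisher's exact test across gene models, which are not independent. Since both risers and fallers were over-represented, the overlaps give no direction relative to ripening.

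Quantile normalization gave 311 higher and 391 lower gene models in place of 141 and 453. The count fell to 130 with sugar content in the model, to 64 on plot means, to 121 without replicate 1 and to 141 without replicate 3, and to between 337 and 367 without day 28 of 2014, day 28 of 2013 or day 21 of 2012, and rose to 964 without day -18 of 2012 and to 907 without replicate 2 of 75% thinning on day 0 of 2012. VIT_01s0011g02710 kept its call under all 12 alternatives, and VIT_18s0001g11520, VIT_08s0040g00490 and VIT_08s0040g00920 lost theirs under 5, 2 and 3 of them.

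Single seasons gave 206 called gene models in 2012 (25 higher, 181 lower), 13 in 2013 (6 higher, 7 lower) and 31 in 2014 (14 higher, 17 lower). The thinning effect differed between seasons in 6 gene models (limma moderated F-test), with 1476 below an unadjusted p of 0.05. For VIT_17s0000g07260, which had the smallest adjusted p (0.00748) of these 6 in the limma F-test, the difference was -0.18 in 2012, 0.22 in 2013 and -0.04 in 2014 on the log2 scale. With quantile normalization the 2012 split was 90 higher and 134 lower, and in 2013 it was 16 higher and 8 lower. The counts of single seasons depended on single days. In 2012 the count was 594, 1129, 470, 72, 82, 135 and 115 without day -28, -18, -9, 0, 11, 21 and 32 in turn, and 749 without replicate 2 of 75% thinning on day 0. In 2013 it was 29, 36, 27, 42, 5, 3, 8 and 6 without day -14, -7, 0, 7, 21, 28, 35 and 37. In 2014 it was 61, 71, 16, 18, 8, 11 and 7 without day -14, -6, 14, 21, 28, 35 and 42, and 9 without replicate 2 of 50% thinning on day 28. Without replicate 1, 2 and 3 the counts were 34, 2787 and 181 in 2012, 0, 70 and 1 in 2013, 9, 100 and 0 in 2014 and 5, 1629 and 0 for the test between seasons (limma, with 1124, 796 and 931 gene models below an unadjusted p of 0.05 at the counts of 0). Sugar content in the model gave 7 in 2012 and 63 in 2014, and plot means gave 0, 5 and 1 in 2012, 2013 and 2014 (limma, with 849 below an unadjusted p of 0.05 in 2012). The test between seasons gave 2 gene models with a pseudocount of 0.1, 10 without the filter and 3 without days -28 and -18 of 2012.

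Before veraison 416 gene models differed between the thinning levels, 106 higher and 310 lower at 75%. Chance was not excluded for this count. As many calls came from 5 of 100 splits of single libraries and from 5 of 100 of whole replicate numbers. Of the 106 higher ones, 85 belonged to the fallers of ripening where 23.6 were expected, and of the 310 lower ones 75 belonged to the risers where 23.7 were expected (Fisher's exact test across gene models, adjusted p = 1.26e-35 and 4.64e-19). Day -18 of 2012 and day -14 of the later seasons are also the green stage of the ripening change, so both use some of the same libraries. Across all gene models the thinning difference before veraison correlated with the ripening change at r = -0.28, where gene models are not independent replicates. On single days it was -0.18, 0.10 and -0.32 on days -28, -18 and -9 of 2012, -0.21 and -0.29 on days -14 and -7 of 2013, and -0.07 and 0.05 on days -14 and -6 of 2014. The count was 80 without day -14 of 2013, 226 without day -6 of 2014 and 1120 without day -18 of 2012, 680 without the filter on low values, 153 and 172 without replicate 1 and 3, and 0 on plot means (limma, with 1400 below an unadjusted p of 0.05).

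From veraison to day 14 the relation to ripening was the opposite, for the means of both phases. Of 724 called gene models 131 were higher and 593 lower at 75% thinning, and 481 of the 593 lower ones were fallers of ripening where 132 were expected. Of the 131 higher ones 64 were risers where 10.0 were expected. These overlaps had adjusted p of 1.25e-209 and 1.26e-35 by Fisher's exact test across gene models, which are not independent. Of 100 splits that moved single libraries within days, the real one included, 8 gave as many calls as the 724. Of 100 that moved whole replicate numbers, 31 did, so chance was not excluded for that count. The correlation with the ripening change was 0.38 across gene models for the mean of the phase, while single days differed. It was 0.11 and 0.19 on days 0 and 11 of 2012, 0.33, 0.45 and 0.00 on days 0, 7 and 14 of 2013, and -0.16, -0.07 and 0.47 on days 0, 7 and 14 of 2014. The thinning difference from veraison to day 14 itself differed from that before veraison in 1173 gene models, 465 upward and 708 downward (limma, adjusted p under the threshold of 0.05). The count of 724 fell to 35 without day 14 of 2014, and to 295, 422, 387 and 313 without days 0 and 11 of 2012 and days 0 and 7 of 2013. It was 37 with sugar content in the model, 16 on plot means, 3 and 249 without replicate 1 and 3, 3135 without replicate 2, and 1587 without replicate 2 of 75% thinning on day 0 of 2012, while quantile normalization gave 251 higher and 446 lower gene models.

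From day 21 to harvest 1032 gene models differed between the thinning levels, 221 higher and 811 lower at 75%, with a median absolute log2 difference of 0.21. As many calls came from 2 of 100 splits of single libraries. Of 100 splits of whole replicate numbers 8 gave as many, so chance was not excluded at that level. VIT_08s0007g05830 was higher, at 3.38 RPKM at 75% against 1.65 at 50% thinning (33 libraries each, listed at 0 in 1 of those at 50%), by 0.73 ± 0.08 log2 (SE, limma, adjusted p = 1.65e-10). VIT_08s0040g00490 stood at 9.95 ± 4.95 RPKM against 5.53 ± 4.83 (SD, n = 33 each), a log2 difference of 0.93 ± 0.15 (SE, limma, adjusted p = 3.14e-06). VIT_08s0040g00920 was lower, at 6.92 ± 14.2 against 17.0 ± 23.9 RPKM (SD, n = 33 each), by -1.31 ± 0.26 log2 (SE), and VIT_02s0025g04270 at 50.4 ± 63.0 against 98.7 ± 103 RPKM, by -0.96 ± 0.22 (SE). Among the 811 lower gene models 286 were fallers and 135 were risers of ripening, where 181 and 62.1 were expected. Of the 221 higher ones 69 were risers where 16.9 were expected. The highest adjusted p of these overlaps was 2.08e-17 by Fisher's exact test across gene models, which are not independent. Both risers and fallers were over-represented among the lower gene models, so that overlap gives no direction relative to ripening. The libraries of day 21 enter both this phase and the ripening change. VIT_02s0025g04270 lost its call without replicate 3 and on plot means (limma, adjusted p = 0.0598 and 0.0692). The thinning effect differed from that before veraison in 726 gene models and from that of veraison to day 14 in 114. Without day 21 or day 32 of 2012 the count was 382 and 491, without replicate 1, 2 and 3 it was 252, 601 and 518, and with sugar content in the model it was 597. Plot means gave 703, and quantile normalization gave 419 higher and 600 lower gene models.

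**Figure D2:**
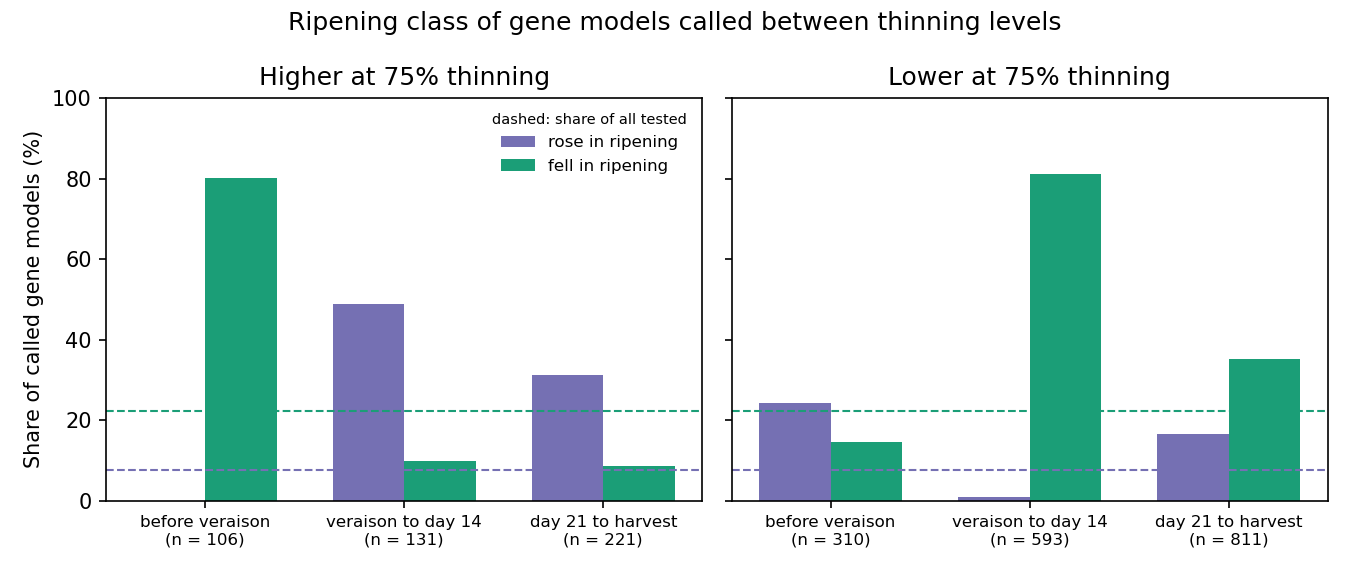
Share in percent of the gene models called between thinning levels that rose (purple) or fell (green) in ripening, for gene models higher (left) and lower (right) at 75% thinning in 3 phases; dashed lines mark the share of all tested gene models. Fallers made up 80.2% of the higher gene models before veraison and 81.1% of the lower ones from veraison to day 14, against 22.3% of all gene models.

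On single days most calls fell before veraison, with 4291 gene models on day -28 and 3390 on day -18 of 2012 and 511 on day -14 of 2013. Gene models called on both days of 2012 numbered 1785, and 1773 of these had opposite signs. The differences of these days correlated at r = -0.62 across gene models. The r was 0.03 with 1 library left in the group of 50% thinning on day -18, without its replicate 1 and 2. These 2 libraries correlated with replicate 3 of their group at 0.925 and 0.956, against a median of 0.987 between replicates. Later, 265 were called on day 0 of 2012, 321 on day 14 of 2014, 127 on day -6 of 2014 and 78 on day 7 of 2014. On days 0, 35 and 37 of 2013 and days 0 and 35 of 2014 limma called 0 gene models, with 716, 1092, 426, 408 and 627 below an unadjusted p of 0.05. A share of 0.05 of the 20460 gene models tested is expected below that value without any difference. Without any 1 library the count of day -28 of 2012 lay between 3089 and 3763, while the counts of the 6 other days below, all with at least 78 calls, rested on single libraries. On day -18 of 2012 the count was 1258, 1518 and 7891 without replicate 1, 2 and 3 of 50% thinning and 1994 without replicate 1 of 75% thinning. On day 0 of 2012 it was 79, 479 and 108 without replicate 1, 2 and 3 of 50% thinning and 803, 5896 and 592 without those of 75% thinning. On day 7 of 2014 it was 2, 160 and 2 and then 22, 36 and 9 in the same order. On day -14 of 2013 the count was 152 without replicate 3 of 50% and 869 and 263 without replicate 2 and 3 of 75% thinning. On day -6 of 2014 it was 433 without replicate 1 of 50% and 679 without replicate 2 of 75% thinning, and on day 14 of 2014 it was 183 and 213 without replicate 2 and 3 of 50% and 83 without replicate 3 of 75% thinning.

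**Figure D3:**
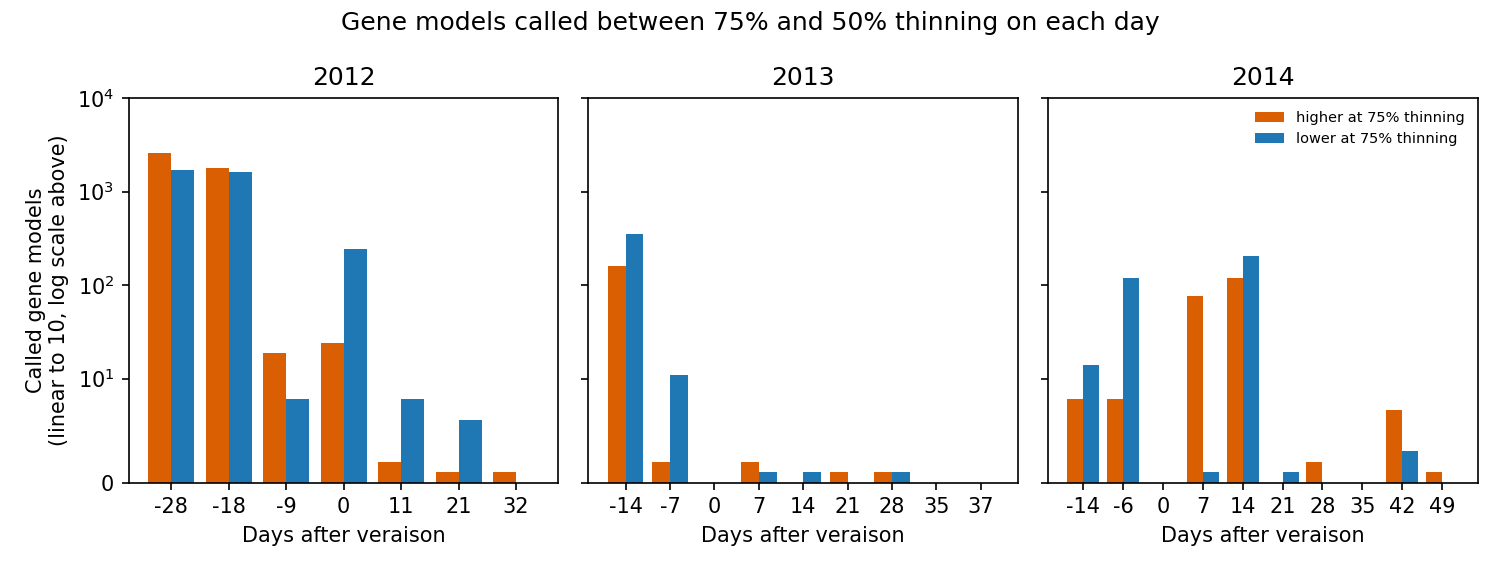
Number of gene models called higher (orange) and lower (blue) at 75% than at 50% thinning on each matched day, against days after veraison; the vertical axis is linear up to 10 and logarithmic above. The largest counts were 4291 and 3390 gene models on days -28 and -18 of 2012.

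The ripening change itself differed between thinning levels in 205 gene models, 104 more upward and 101 more downward at 75% thinning. Chance was not excluded by 100 splits that moved single libraries within days, of which 10 gave as many calls (highest other 3690). Of 100 that moved whole replicate numbers, 3 did (highest other 274). With day -9 of 2012 in place of day -18 the count was 47. It was 2, 444 and 121 without replicate 1, 2 and 3.

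Seasons were compared on day 21, when the mean sugar content of the 6 groups lay between 20.01 ± 0.80 and 21.42 ± 0.48 g per 100 ml (SD, n = 3). The ripening score at 50% and 75% thinning was 6.79 ± 0.10 and 6.83 ± 0.06 in 2012, 7.36 ± 0.14 and 7.56 ± 0.18 in 2013 and 6.29 ± 0.30 and 6.42 ± 0.18 in 2014 (SD, n = 3 each), from gene models that differ between seasons, so an equal stage of ripening was not shown. Between 2013 and 2012, 364 gene models differed (111 higher, 253 lower in 2013), between 2014 and 2012, 518 (21 higher, 497 lower in 2014), and between 2014 and 2013, 538 (106 higher, 432 lower in 2014). VIT_18s0001g13240 stood at 754 ± 135 RPKM in 2012 and 664 ± 53 in 2013 (SD, n = 6 each) and at 0 to 0.475 RPKM in 2014, with log2 differences of -9.31 ± 0.16 and -9.14 ± 0.16 (SE, limma, adjusted p = 2.87e-83 and 2.09e-82). VIT_18s0041g00720 lay between 554 and 1093 RPKM in 2012 and was listed at 0 in 5 of 6 libraries of 2013 and in 5 of 6 of 2014, with 32.3 and 28.1 RPKM in the remaining ones. VIT_03s0038g02790 was listed at 0 in all 6 libraries of 2013 and in 1 of 6 of 2012, where it reached 803 RPKM (it lost the call without replicate 2, limma, adjusted p = 0.0869), and VIT_13s0067g01160 was listed at 0 in 5 of 6 libraries of 2014, with 321 RPKM in the remaining one, and lay between 70.1 and 839 RPKM in 2013. VIT_19s0085g00740 was higher in 2014 than in 2012 (17.9 ± 16.2 against 3.56 ± 2.08 RPKM, SD, n = 6 each), by 1.75 ± 0.42 log2 (SE, limma, adjusted p = 0.000695). Season cannot be told apart from any batch of libraries or processing that follows it, and 96 of the 497 and 94 of the 432 gene models lower in 2014 had a median RPKM below 0.1 over the libraries of that season. With a pseudocount of 0.1 the counts were 755, 897 and 1048, and quantile normalization gave 74 higher and 290 lower gene models between 2013 and 2012.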

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

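The tests of the explanations weighed here and the splits of whole replicate numbers were chosen after the results were seen. So were the tests of sugar and score by phase, the differences between phases and the difference between days -28 and -18 of 2012. What each outcome would mean, for the counts over other splits of the samples as well, was written down after those results were seen. No group was large enough for a test of outlying samples, since all 55 groups held 3.

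These results concern a thinning effect that differed between groups of samples, by a test of the difference, set against 100 splits that moved single libraries within days and 100 that moved all libraries of a replicate number within a season together, the real split included. The latter bear on samples of the same plot, if a number stands for 1 plot, which the labels do not say. The effect differed between veraison to day 14 and the days before veraison in 1173 gene models (2 splits of single libraries gave as many, highest other 2219, and 3 of whole numbers, highest other 1752). Between day 21 to harvest and before veraison it differed in 726 (2 splits, highest other 806, and 1, highest other 240). For both of these chance was excluded by both kinds of split, at a share under 0.05 that was not adjusted over the contrasts. Both contrasts were chosen after the results were seen. Neither was rerun under the alternatives, such as without single days or replicate numbers, on which the counts of their phases depended. Chance was excluded by neither kind of split for the 114 between day 21 to harvest and veraison to day 14 (9 splits, highest other 2751, and 9, highest other 1006). The ripening change differed between thinning levels in 205 (10 splits of single libraries, highest other 3690, so chance was not excluded, and 3 of whole numbers, highest other 274). Between seasons the effect differed in 6 gene models, and chance was not excluded (21 splits of single libraries, highest other 2856). The sugar difference was larger by 1.35 g per 100 ml, and the score difference by 0.80, from veraison to day 14 than before veraison (permutation test, adjusted p = 0.00012 and 0.0262), in tests that treat the samples of different days as independent.

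The counts of the thinning contrasts were set against the same splits. With single libraries moved, chance was excluded for the 594 gene models over all seasons (3 of 100 splits, highest other 1127) and the 1032 from day 21 to harvest (2 of 100, highest other 1060). With whole replicate numbers moved it was not, for either count (16 of 100, highest other 6620, and 8 of 100, highest other 3479). For the 13 of 2013 chance was excluded with single libraries moved (1 of 100, highest other 3), while whole numbers allow 10 splits, too few for a share under 0.05 (1 gave as many, highest other 1). With single libraries moved it was not excluded for the 206 of 2012 (18 of 100, highest other 6379), the 31 of 2014 (11 of 100, highest other 63), the 416 before veraison (5 of 100, highest other 1056), the 724 from veraison to day 14 (8 of 100, highest other 4994) or the 9084 calls summed over single days (30 of 100, highest other 20988). With whole numbers moved it was not excluded for the 416 (5 of 100, highest other 605) or the 724 (31 of 100, highest other 4976). Splits that call several times the real number, as in 2012, point to a structure of the libraries, whose nature was not tested. For ripening (6124 gene models, highest other 1920), 1 of 100 splits, the real one, gave as many. The same held for 2013 against 2012 (364, highest other 194), 2014 against 2012 (518, highest other 323) and 2014 against 2013 (538, highest other 280). This excludes a random division of the libraries only. Season coincides with any batch of libraries or processing that follows it, so these splits cannot tell season from batch.

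On days -28 and -18 of 2012 the 75% minus 50% differences ran in opposite directions (r = -0.624 across gene models) and changed between the days in 6510 gene models (2 of 100 splits of single libraries gave as many, highest other 6848). The negative correlation rested on replicate 1 and 2 of 50% thinning on day -18. Without 1 of them r was -0.52 or -0.50, and without both it was 0.03, with 1 library left in that group. With replicate 2 or replicate 1 as the only library kept, r was -0.64 or -0.55. Replicate 1 and 2 correlated with replicate 3 at 0.925 and 0.956, while replicate 3 correlated with the 50% libraries of day -28 at 0.985 to 0.988. Neither a thinning effect of the same direction on both days nor one that turned between them was thus excluded. Of the 6 libraries of 50% thinning, 5 correlated more with the 75% libraries of the other day than with those of their own. On the other pairs of consecutive days at most 3 did. An exchange of libraries between the days may thus be part of the pattern. A 1 for 1 exchange of 50% libraries would move as many from each day, so it could not leave just 1 in place. Of the 12 libraries of these days 4 were nearest to another group, each to a library of the other day, against 49.7% of the others. This share cannot decide on an exchange, since libraries exchanged as a whole group stay nearest to each other. Recorded sugar followed the labels (0.48 to 0.59 on day -28, 0.93 to 1.29 on day -18). It is itself a label of the samples, so it cannot decide either. A difference in ripening stage stays open, since the day -28 and day -18 differences correlated with the developmental step from day -14 to day -7 of 2013 at r = -0.201 and 0.19. Their r was -0.32 and 0.36 with the step from day -18 to day -9 of 2012 and -0.13 and -0.18 with that from day -28 to day -18, steps that share libraries with the differences.

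A set of 108 gene models had median RPKM of at least 1 in 2012 and in 2013 and below 0.1 in 2014, against 13 such models for 2012 and 4 for 2013. Outside this set by its 2014 median of 0.263, VIT_18s0001g13240, chosen after its values were seen, lay between 132 and 1343 RPKM in all 48 libraries of 2012, between 111 and 1065 in all 54 of 2013 and between 0 and 2.84 in the 63 of 2014, as 1 of 24 gene models more than 8-fold lower in every library of 2014. Of 12 gene models whose values equalled those of another model to 4 decimals in all 102 libraries of 2012 and 2013, 12 were listed at 0 in 2014, against a 2014 median of 0 in 6.05% of 12966 other models of the same levels. Reads shared between identical gene copies may thus have been counted differently in 2014, but 4 of these 12 models reached the levels of the set, and for the rest of the set this was not tested. Weather or vine differences cannot be told apart from it, because season and processing coincide and the 13 models near 0 in 2012 alone set no bound.

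Of the 724 gene models called between thinning levels from veraison to day 14, 529 were also called after quantile normalization, which argues against the authors' scaling as the whole cause, although lower calls went from 593 of 724 to 446 of 697, so part of their excess depends on it. With sugar content in the model 37 were called (82 without day 0 of 2014, where recorded sugar lay below that expected from the score), and the median log2 difference of the 724 went from 0.24 to 0.19 while its median SE went from 0.063 to 0.071. The lost calls thus go with slightly smaller differences and less precision. Since each group had its own mean, the slope on sugar came only from the scatter between samples of a group. It did not use the rise of sugar over ripening. Sugar itself differed by 1.16 g per 100 ml, so it stays open whether berries at 75% thinning were further in ripening. Dependence between samples of the same plot stays open too, since plot means gave 16 calls and deviations of the same replicate number on consecutive days correlated at 0.10, 0.21 and 0.13 at 75% thinning in 2012 and from -0.05 to 0.06 in the other groups of plots. As a hypothesis that these tests did not decide, stronger thinning may advance ripening after veraison, but the ripening score differed by 0.33 (permutation test, adjusted p = 0.0769) and by 0.15 (p = 0.408) without day 14 of 2014, and the 724 fell to 35 without that day.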

How the results depend on the processing

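Replicates left out by number or singly, days left out and gene models left out are described in processing; the settings without days -28 and -18 of 2012, without single libraries, with day -9, without day 0 of 2014 (for sugar, and with sugar content in the model) and without gene models near 0 in 2014 were chosen after the data were seen. Ripening stayed within 1.5 times of 6124 under all 8 alternatives, and the causes of the other changes were not tested.

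With a pseudocount of 0.1 the season contrasts were 755, 897 and 1048 gene models (2013 against 2012, 2014 against 2012, 2014 against 2013) and the thinning by season test gave 2. Without the filter, thinning before veraison gave 680 and thinning by season 10. Quantile normalization gave 24 for thinning in 2013. Replicate number as a block changed no call of gene models by over 1.5 times (615 over seasons, 218, 14 and 37 by season, 427, 797 and 1074 by phase, 9837 on single days, 264 for thinning by ripening, 8 for thinning by season), and the numbers did not pair the samples of the 2 thinning levels (same-number r of -0.08 to 0.12), although over consecutive days the 3 numbers of 75% thinning in 2012 deviated together (r of 0.10, 0.21 and 0.13). Paired by number, the sugar differences of 0.71 in 2012 and 0.52 in 2013 had an exact sign-flip p of 0.25 each, the smallest that 3 pairs allow.

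Without 1 replicate number in turn, thinning gave 121 to 524 gene models over seasons, 34 to 2787 in 2012, 0 to 70 in 2013, 0 to 100 in 2014, 153 to 511 before veraison, 3 to 3135 from veraison to day 14, 252 to 601 from day 21 to harvest, 4142 to 15946 on single days, 2 to 444 for thinning by ripening and 0 to 1629 for thinning by season. The counts of 0 came from limma, without replicate 1 in 2013 and without replicate 3 in 2014 and for thinning by season, with 1124, 796 and 931 below an unadjusted p of 0.05. The sugar difference ranged from 0.559 to 0.944 in 2012, from 0.41 to 0.64 in 2013 and from -0.15 to 0.468 in 2014, and the score difference of 2012 from -0.11 to 0.141. That score difference was also below 0 with a pseudocount of 0.1 (-0.0109), with quantile normalization (-0.0358) and without replicate 3 (-0.0113), none past the threshold.

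Sugar content as a covariate gave 130 over seasons, 7 in 2012, 63 in 2014, 37 from veraison to day 14 (82 without day 0 of 2014) and 597 from day 21 to harvest. Plot means gave 64, 0, 5 and 1 over seasons and in 2012, 2013 and 2014, and 0, 16 and 703 in the 3 phases (limma, with 849 in 2012 and 1400 before veraison below an unadjusted p of 0.05). Without days -28 and -18 of 2012 the single days gave 1403 and thinning by season 3. Without replicate 2 of 50% thinning on day 28 of 2014 that season gave 9 and day 21 to harvest 801. Without replicate 2 of 75% thinning on day 0 of 2012, thinning gave 907 over seasons, 749 in 2012 and 1587 from veraison to day 14. Day -9 in place of day -18 gave 47 for thinning by ripening. Without the 108 gene models near 0 in 2014 the contrasts of 2014 with 2012 and 2013 gave 422 and 444.

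Named gene models kept their direction under the alternatives run for each; 13 of these values lost the threshold and 160 kept it. The gene list tests, with preset and estimated correlation, were not run because no gene model had a name. RPKM without read counts leaves the depth behind small values unknown.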

Other observations

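The sugar values of day 0 of 2014 were set against the ripening score after they had been seen. All 6 samples were recorded at 1.4 to 2.15 g per 100 ml, close to 1.71 ± 0.07 at 50% and 1.76 ± 0.27 at 75% thinning on day -6 (SD, n = 3 each). A smooth relation of sugar to score in the other 159 samples gave 5.61 to 8.23 g per 100 ml for the scores of these 6, so the recorded values differed from these by a mean of -5.14, or -2.00 residual SDs. All 6 lay below, by -3.60 to -6.75 g per 100 ml. The largest absolute residual among the 159 samples was 8.11 g per 100 ml, so a single sample can lie as far off. That value does not bear on 6 samples of 1 day lying off in the same direction. The 8 other samples with scores near theirs held 3.06 to 12.0 g per 100 ml, above all 6 recorded values. The only one of 2014 among them was replicate 2 of 75% thinning on day 7, at 12.0. Both this set and the smooth relation pooled the seasons, whose scores use different gene models. An exchange of libraries with day -6 is argued against, because the lowest score of day 0 (-0.0401) lay above the highest of day -6 (-2.60), and the sugar records of that day stay open. Without day 0 the sugar difference of 2014 was 0.20 g per 100 ml (permutation test, p = 0.538).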
